A study of Mus musculus with 2 samples.

How the data were processed

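H3K4me1 (histone H3 carrying a single methyl group on lysine 4, a mark of enhancers and of the flanks of gene starts) was measured by chromatin immunoprecipitation followed by sequencing in midbrain of mouse embryos of the B6NCrl strain at embryonic day 15.5. There were 2 biological replicates of 1 group, each a pool of both sexes, of 78 embryos in replicate 1 and 62 in replicate 2. The series held no second tissue, age or mark, so no comparison between groups was possible, and 2 replicates allow no test between them. Values are given for each replicate or as mean ± SD (n = 2).

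The starting material was 4 peak lists on the mm10 build: 1 per replicate, 1 called on both replicates together (the pooled list) and 1 the authors named replicated. Per the file headers of the accompanying text files, replicate 1's list was derived from 1 alignment and 2 other files, and replicate 2's from 1 alignment and 1 other file. The pooled list was derived from 2 alignments and 2 other files, and the replicated list from the 3 other peak lists. What those other files hold is not stated, and so the replicates may differ in their controls. The aligner, the peak caller, their versions and thresholds are not given in the sources used here. Each deposited list gives a fold enrichment, a ratio of the peak over control, which was used to rank and describe peaks within a list, to set the upper quartile on the X chromosome beside that on autosomes, and to choose peaks of like fold in the replicates' lists. The deposited p-values and q-values are on a −log10 scale (neg_log10_p); the smallest −log10 p was 2.05 in replicate 1 and 2.03 in replicate 2, and the largest q was 0.242 and 0.337, so the lists reach down to weak peaks, while the median −log10 p was 5.86 and 5.27. The deposited display score was not used, and neither was the other deposited column, the offset of the peak summit. Read totals were not used here, so sequencing depth is unknown, and a place without a peak is not a place without the mark. The 95% Wilson intervals given for shares of peaks cover counting error only.

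Peaks on the 21 assembled chromosomes were used, which left out 5 peaks of replicate 1, 4 of replicate 2, 9 of the pooled list and 3 of the replicated list. Chromosome lengths of the reference (GRCm38, with GENCODE M21 gene annotation) equalled those of mm10. Assembly gaps of at least 100 unknown bases were left out of all densities and random placements. Genes were the 21911 protein-coding symbols on these chromosomes, with the annotated 5′ end as the start. A start was CpG-rich when the 1 kb around it had a CpG observed/expected ratio of at least 0.6 and a GC content of at least 50%, and CpG-poor otherwise.

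A peak counted as shared when the overlap reached 50% of the length of either peak. Chance was estimated from 100 random placements of the peaks on the same chromosome without overlap, and from 20 placements in each alternative setting. Peak midpoints were assigned to promoter (within 1 kb of a gene start), then exon, intron and intergenic sequence. The profile around gene starts took the share of starts covered at each 100 bp from 5 kb upstream to 5 kb downstream, and the dip was the mean of the highest shares on either side minus the share at the start.

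For 20 gene lists and 4 gene families fixed before the data were examined, 2 values were computed: the share of members with a replicated peak within 2.5 kb of the start, and the median percent of the locus (gene with 10 kb on each side) covered by replicated peaks. Each was set beside 10000 random lists of the same size drawn with replacement from other protein-coding genes in the same of 20 length bins, with tied lists split evenly in the percentile. A list was called high or low when it lay in the upper or lower 2.5% of its random lists. With 24 lists and 2 measures, some calls arise by chance, and the percentiles describe these libraries, since genes are not replicates. The percent of a locus that is covered itself changes with the window and with the peaks counted, so lists were compared across such settings by percentile. A locus takes in neighbouring genes, and 13 genes stood in more than 1 of the 20 lists. That count leaves out the 4 families, whose members also stand in the lists, Irx1 and Rplp0 among them. The 24 lists and families are therefore not independent. The genes named are the 2 members of each list with the highest locus coverage and the 1 with the lowest, the genes at the 10 domains with the most covered bases, and the 5 genes of at least 10 kb with the highest coverage; any others are named as examples chosen after their values were seen.

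Broad domains were replicated peaks merged when within 3 kb of each other. For 12 fixed sequences, occurrences per kb on both strands in replicated peaks over 2.5 kb from any gene start were divided by those in random places of the same width on the same chromosome and in the same 5% GC bin. The error of the log2 ratio is a jackknife standard error over chromosomes. The control planned for composition was the reversed sequence; since reversal can make or remove a CpG, all other orders of the same bases with as many CpG were added as a control after the data were seen.

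Alternatives were each replicate's own list, peaks with a q-value of at most 0.0001, peaks in the upper part of the list by fold, other overlap rules, promoter windows, gene sets, CpG limits, locus sizes, matching and merging distances, and a 100 kb shift in place of random placement. Keeping only replicated peaks overlapped in both replicates, and matching families of gene symbols on CpG class, were alternatives added after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data. They recovered a planted share of overlapping peaks and a planted sequence enrichment, and called random gene lists no more often than the nominal rate. A moderate increase in the coverage of a list's members was often missed, so a list that was not called may still differ.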

Results

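The data were peaks of H3K4me1 in mouse midbrain at embryonic day 15.5, from 2 replicate pools of embryos. Replicate 1 had 169902 peaks covering 86.6 Mb and replicate 2 had 140920 covering 64.2 Mb, a mean of 75.4 ± 15.9 Mb (SD, n = 2). Median peak width was 336 bp in replicate 1 and 310 bp in replicate 2, and median fold enrichment over control was 2.95 and 3.01. The pooled list held 184078 peaks. The replicated list held 113571 peaks with a median width of 535 bp, covering 84.0 Mb or 3.17% of the non-gap genome. Read depth is unknown, because the deposited lists carry no read totals.

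The first comparison asked how far the 2 pools of midbrain marked the same places. Of replicate 1 peaks, 53.8% were shared with replicate 2 (91353 of 169897, 95% Wilson interval 53.5 to 54.0), and of replicate 2 peaks 72.4% were shared with replicate 1 (101961 of 140916, interval 72.1 to 72.6). Random placement gave 4.04% and 4.88%, so sharing was 13.3 and 14.8 times that of chance. The 2 lists had 48.4% of their combined bases in common, against 1.62% by chance. Sharing rose with peak strength: in the weakest of 5 equal bins by fold, 26.0% of replicate 1 peaks and 54.3% of replicate 2 peaks were shared, and in the strongest bin 94.6% and 97.1%. The bins also differed in width, from a median of 238 bp to 868 bp in replicate 1 and from 230 bp to 728 bp in replicate 2. A wide peak counts as shared when it holds a small one, and chance was not estimated by bin, so strength and width were not separated. When peaks were shifted by 100 kb in place of random placement, chance sharing was higher and the ratios were 7.18 and 7.81. When at least 75% of both peaks had to overlap, 15.8% and 19.1% were shared.

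**Figure D1:**
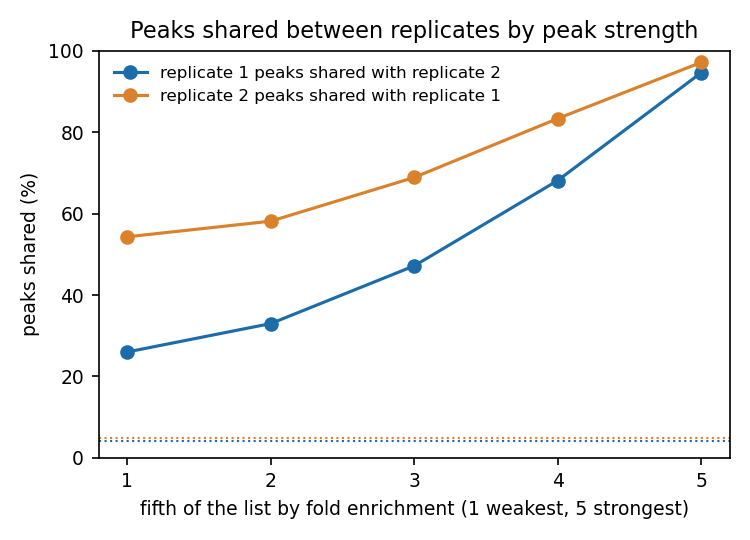
Percent of each replicate's peaks shared with the other replicate (vertical axis) in 5 equal bins of fold enrichment from weakest to strongest (horizontal axis), with dotted lines for the mean of random placements over all bins together. Both lines climb, from 26.0% to 94.6% in replicate 1 and from 54.3% to 97.1% in replicate 2.

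The replicated list was a subset of the pooled list. All 113568 of its peaks on assembled chromosomes had the coordinates and values of a pooled peak, and they made up 61.7% of pooled peaks. In the weakest of 5 bins of pooled peaks by fold, 21.01% were in the replicated list, and in the strongest 99.7%. The list was not limited to peaks called in both replicates: 88623 peaks (78.0%) overlapped a peak of each, and 24945 (22.0%) lacked an overlap with one or both. The peaks that lacked one or both had a median fold of 2.60, and the others 3.27. All 88623 pooled peaks that overlapped both replicates were in the list.

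H3K4me1 peaks in midbrain lay mostly within genes and away from gene starts, while promoters held far more of them than chance placement gave. Introns held 53.8% of replicated peaks, intergenic sequence 29.4%, promoters 11.2% and exons 5.67%. Promoters held 6.61 times the chance share, exons 1.60 times and introns 1.45 times, and intergenic sequence 0.511 times. In the replicates' own lists the promoter share was 9.68% ± 0.803 and the intron share 55.0% ± 0.136 (SD, n = 2). With all annotated genes in place of protein-coding genes the promoter ratio was 3.72, and with a promoter of 2.5 kb on either side the promoter share was 21.7%. Against a 100 kb shift, exons and introns were close to chance, at 1.099 and 1.108 times.

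At CpG-rich gene starts the mark flanked the start and spared the start itself. Of 9725 CpG-rich starts, 12.6% were covered by a replicated peak at the start, 48.9% at 600 bp upstream and 66.6% at 1100 bp downstream, the highest shares on either side. The dip was 45.1 percentage points in the replicated list and 40.4 ± 1.79 in the replicates' own lists (SD, n = 2). The 12186 CpG-poor starts had 15.6% covered at the start and a dip of 1.17 points, against 0.825 ± 0.505 in the replicates. A replicated peak lay within 2.5 kb of 97.3% of CpG-rich starts and 38.1% of CpG-poor starts, and of 64.4% of all starts (14105 of 21911). With a lower CpG limit the CpG-poor class had 9.39% of starts covered and a dip of 0.010, and with every transcript start its dip was 4.32.

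**Figure D2:**
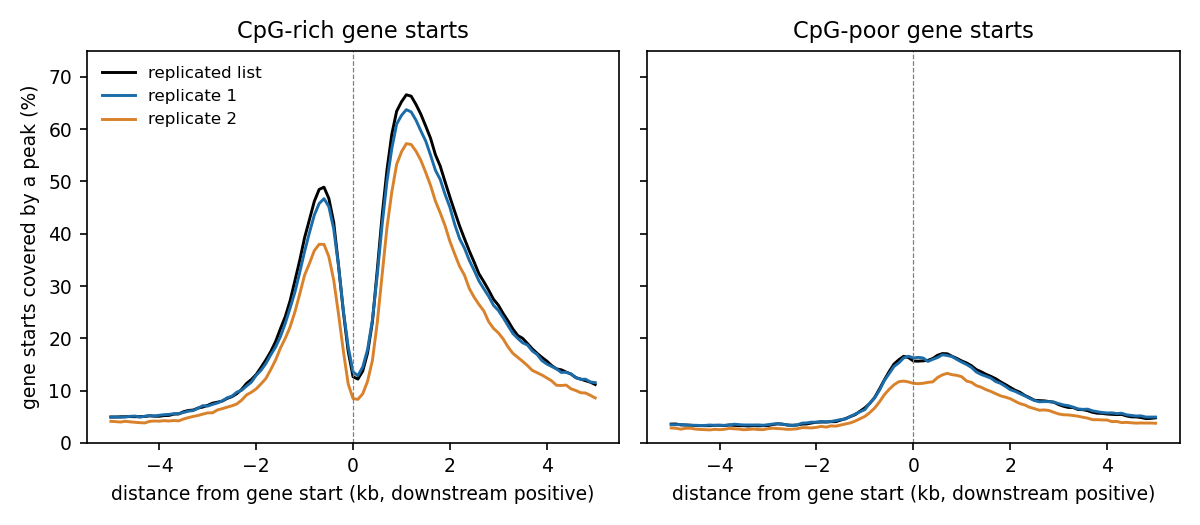
Percent of protein-coding gene starts covered by a peak (vertical axis) by distance from the start in kb (horizontal axis), for CpG-rich starts on the left and CpG-poor starts on the right, in the replicated list and in each replicate's own list. CpG-rich starts fall to 12.6% at the start between flanks of 48.9% and 66.6%. CpG-poor starts form a low rise with 15.6% covered at the start and at most 17.1% beside it, and 3.59% at 5 kb upstream.

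The midbrain patterning and dopaminergic lists were both called high for locus coverage by H3K4me1 peaks. So were lists not particular to midbrain, among them housekeeping genes with a median of 13.9%. In the midbrain patterning and tectum list the median locus was 21.2% covered by replicated peaks, against 4.18% in random lists of equal gene length and 8.78% in lists matched on CpG class too, and 27 of 28 members had a peak near the start. Both values lay above all 10000 random lists matched on gene length alone, and the replicates gave 18.5% ± 4.30 (SD, n = 2) for the locus. With matching on CpG class too, the share with a peak near the start was still high, at percentile 99.035. The median share of those random lists was 85.7%. The homeobox genes Irx1 (chromosome 13, 71957921 to 71963723) and Irx3 (chromosome 8, 91798525 to 91802067) led the list, with 44.1% and 40.5% of their loci covered, and the transcription factor gene Tfap2b was lowest, at 3.94%. The dopaminergic list had a median of 10.3%, at percentile 99.8 of random lists (replicates 9.33% ± 2.97), and 17 of 20 members had a peak near the start, a share at percentile 95.7 and not called high. Its highest members were En2, a homeobox gene of midbrain and anterior hindbrain, at 31.7% (replicates 24.1% ± 16.8), and Pitx3, a homeobox gene needed by midbrain dopamine neurons, at 25.9%. Aldh1a1, a retinaldehyde dehydrogenase of a subset of dopamine neurons, was lowest at 0.130%. In replicate 2's own list En2 had 12.2% and Irx3 26.5%. The coverage of Tfap2b by replicated peaks lay outside the gene body. The dopaminergic locus call ended with 50 kb on each side (percentile 62.7) and with only peaks above the median fold (91.5), and its promoter share was called high with a window of 1 kb (98.4).

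Progenitor and neuronal lists were also covered widely. Neural progenitor and radial glia genes had the highest list median, 23.8% (replicates 19.6% ± 2.73, SD, n = 2), with 20 of 22 near-start peaks; Hes5, a Notch target, had 43.7% of its locus covered and Ascl1, a proneural factor, 43.1%, while Ptprz1, a receptor phosphatase of radial glia, had 2.44%. Pan-neuronal genes had a median of 12.4% (replicates 11.3% ± 2.30), led by the RNA-binding protein gene Celf4 at 39.1% and the adhesion gene Ncam1 at 27.0%, with the sodium channel gene Scn2a lowest at 1.401%. GABAergic genes had a median of 18.6% (replicates 17.1% ± 1.59), with Ascl1 and the vesicular GABA transporter gene Slc32a1 (31.6%) highest and Gad2, a GABA-synthesizing enzyme gene, lowest at 5.35%. Glutamatergic genes had a median of 15.2% (replicates 12.54% ± 1.47), from 47.7% for Ebf3 and 31.0% for Neurod2 to 1.65% for Neurod6, all 3 transcription factor genes. In replicate 2's own list Slc32a1 had 16.0%, Gad2 3.03%, Ptprz1 1.401% and Neurod6 none; the coverage of Neurod6 lay outside the gene body, and replicate 1's own list gave it 2.47%. All 4 medians lay in the upper 2.5% of random lists, whose own medians ran from 3.55% to 4.81% with matching on length, and were 8.75% for progenitor and 8.08% for GABAergic genes with matching on CpG class too. Near-start shares were high for progenitor genes and not called for pan-neuronal (17 of 20), GABAergic (13 of 15) and glutamatergic genes (11 of 14). The GABAergic locus call ended with 50 kb on each side (94.0), and the progenitor start call ended with matching on CpG class (92.6). The pan-neuronal start share was high only in replicate 1's own list (97.6), against 66.9 in replicate 2's. The GABAergic start share was high in both replicates' own lists (99.3 and 99.5), with a window of 1 kb (98.6) and with peaks overlapped in both replicates (97.9). The glutamatergic start share was high only with a window of 5 kb (99.8). Matching on CpG class put the 3 start shares at 72.7 (pan-neuronal), 65.7 (GABAergic) and 90.1 (glutamatergic).

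Among the lists for other brain regions and neuron classes, forebrain genes were called high for peaks near their starts, and no list was called for locus coverage. Forebrain regional genes had a peak near 21 of 22 starts, at percentile 99.99, and a median locus of 9.72% (percentile 95.7, replicates 10.2% ± 3.31, SD, n = 2); Bcl11b and Emx2, transcription factor genes of the cortex, had 41.2% and 27.5%, and Satb2, a cortical factor, 4.33%. Hox and hindbrain genes had 18 of 25 near-start peaks (percentile 96.99) and a median locus of 6.42% (percentile 64.3, replicates 6.46% ± 2.34). In that list Egr2 and Mafb, hindbrain segmentation factors, had 35.5% and 33.4%, and Hoxb1 had none. Serotonergic, noradrenergic and motor genes had 11 of 14 near-start peaks (percentile 87.9) and a median locus of 4.59% (percentile 48.8), with Fev, a serotonergic factor, at 20.1%, Isl2, a motor neuron factor, at 15.3% and Dbh, the noradrenaline-synthesizing enzyme gene, at 1.56%, all of it outside the gene body. Dbh had 4.11% in replicate 1's own list and 0.996% in replicate 2's, and Hoxb1 had 0.853% in replicate 1's. With matching on CpG class, the Hox locus median lay at percentile 1.81, on the low side. The forebrain start share stayed high with that matching, at percentile 99.86, where the random lists had a median share of 72.7%. The forebrain locus call became high with gene bodies alone (99.8), with means (98.98), with peaks above the median fold (98.7) and in replicate 1's own list (99.6), and lay at 74.1 with matching on CpG class and 51.8 with 50 kb on each side. The start share of serotonergic, noradrenergic and motor genes was high in both replicates' own lists (99.03 and 99.3) and with a window of 5 kb (98.7), and that of Hox genes in replicate 1's own list (99.6) and with 5 kb (99.1); with matching on CpG class they lay at 77.6 and 14.8.

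Glial and vascular lists lay within the range of random lists on both measures. Oligodendrocyte lineage genes had 11 of 14 near-start peaks and a median locus of 7.18%, with the lineage factor Olig2 at 26.5%, the myelin gene Mog at 21.8% and the X-linked myelin gene Plp1 at 0. Mog had no peak near its start and had 12.3% in replicate 2's own list. Astrocyte and ependymal genes had 9 of 12 and 8.05%, from 32.2% for Sox8 and 28.7% for Foxj1, the ciliogenesis factor, to 3.29% for Aldh1l1. Vascular and meningeal genes had 14 of 19 and 3.54%, with Foxc1, a factor of the meninges, at 20.0% and Sox18, an endothelial factor, at 19.9%, while Cdh5, the endothelial cadherin gene, had none (0.914% in replicate 1's own list).

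Liver, microglial and germ cell genes were low in peaks near their starts, while erythroid, epidermis and gut, and muscle and heart genes were not called low on either measure. Of 19 liver genes found, 2 had a peak near the start, below all random lists, and the median locus had none (percentile 0.915); Apoa2 and Tat, genes of hepatocytes, had 9.35% and 5.45%, and Afp, the fetal serum protein gene, had none; the median was 0.363% in replicate 1's own list. Microglia and haematopoietic genes had near-start peaks at 4 of 16 (percentile 0.075) and a median locus of 1.61% (percentile 4.84), with C1qa and Aif1, genes of microglia, at 18.5% and 17.5% and the B cell gene Cd19 at 0. Germ cell genes had 3 of 16 (percentile 0.015) and 1.72%, with Prm2, a protamine gene, at 12.8%, Nobox, an oocyte factor, at 11.8% and Dazl at 0. Of 11 erythroid genes found, 4 had near-start peaks with a median locus of 1.92%, from 24.1% for Epor and 19.2% for Klf1, genes of red cell formation, to 0 for X-linked Alas2; the median was 0.977% in replicate 2's own list and 0 with gene bodies alone or with peaks above the median fold. Epidermis and gut epithelium genes had 8 of 20 and 3.34%, with Sftpc, a surfactant gene of lung epithelium, at 19.5%, Cdx2, an intestinal factor, at 13.1% and Fabp2 at 0. Muscle and heart genes had 12 of 20 (percentile 58.8) and 6.85% (76.9), with Mylpf at 18.5%, Hand1, a heart factor, at 16.9% and Myh3 at 0 (0.475% in replicate 2's own list). The coverage of Apoa2, Tat, Aif1, Prm2 and Nobox lay outside their gene bodies, and of these 5 genes and Sftpc only Apoa2 had a peak near its start. In replicate 2's own list Sftpc had 12.9%, Cdx2 6.73%, Prm2 8.06%, Nobox 7.67% and Tat 3.11%. With matching on CpG class the microglial start share reached percentile 5.7 and the liver locus 15.9. The liver locus call also ended with gene bodies alone (4.5), with 50 kb on each side (11.3) and with peaks above the median fold (3.06), and the germ cell locus became low with gene bodies alone (1.75) and with means (2.27), and lay at 59.8 with 50 kb on each side.

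Housekeeping, cell cycle and ribosomal protein genes carried peaks beside their starts, and the chemosensory receptor families almost none. Housekeeping genes had 19 of 20 near-start peaks and a median locus of 13.9% (percentile 99.9, replicates 13.1% ± 2.38, SD, n = 2; random lists 5.27%, or 8.37% with matching on CpG class), with Chmp2a at 41.5%, Ywhaz at 32.3% and X-linked Hprt at 1.68%. DNA replication and cell cycle genes had 17 of 17, but a median locus of 6.83% (percentile 67.4), with E2f1 and Aurkb, regulators of the cell cycle, at 26.5% and 25.5% and Mki67 at 1.91%. Ribosomal protein genes had 91 of 96 and 11.5%, both above all random lists, with Rpl18 and Rpl7a at 42.8% and 42.7% and Rpl10l at 0. Olfactory receptor genes had near-start peaks at 3 of 1093 (0.274%, and 0.457% in replicate 1's own list) and vomeronasal receptor genes at 1 of 326, below all random lists, and both had a median locus of 0; the highest were Olfr750 at 9.32%, Olfr90 at 7.83%, Vmn1r4 at 3.32% and Vmn1r21 at 1.27%, while Olfr1 and Vmn1r1 had none. The family of Irx, Lhx, Pou, Sox and Zic genes had 45 of 54 and 15.9%, at percentile 99.995 and above all random lists (median 4.54%, or 9.05% with matching on CpG class), led by Pou3f3 at 53.7% with Irx1 next and the pituitary gene Pou1f1 at 0. In replicate 2's own list Hprt had 0.447%, Olfr750 5.74%, Vmn1r4 1.76% and Pou1f1 0.493%, and the coverage of Olfr90 and Vmn1r21 lay outside the gene bodies. Pou3f3 had no peak within 2.5 kb of its annotated start, and 21.1% of its gene body alone was covered. Matching on CpG class ended the start calls of the cell cycle list (92.3) and of the Irx, Lhx, Pou, Sox and Zic family (65.6), and the locus calls of ribosomal protein genes (51.6) and vomeronasal receptor genes (5.0). Receptor and ribosomal protein genes have close paralogs or pseudogenes, where reads may not map to a single place, and a lack of peaks in them is uncertain for that reason.

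**Figure D3:**
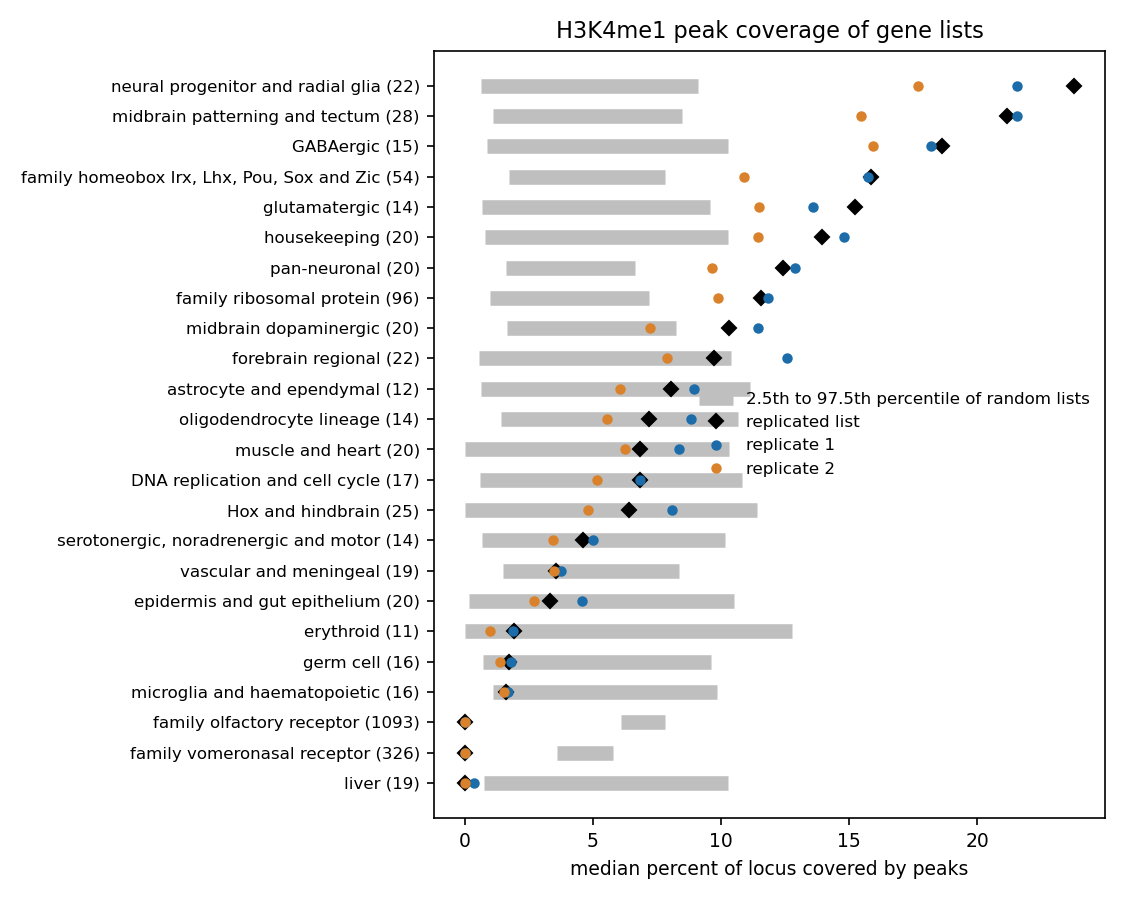
Median percent of the locus covered by H3K4me1 peaks (horizontal axis) for 24 gene lists with their numbers of genes (vertical axis); black diamonds show the replicated list, blue and orange points the replicates, and grey bars the central 95% of random lists. Neural progenitor genes (23.8%) and midbrain patterning genes (21.2%) lie farthest above their grey bars.

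The X chromosome carried far fewer peaks than any autosome. It held 990 replicated peaks, 6.06 per Mb of non-gap sequence, against 47.0 per Mb on the autosomes together, a ratio of 0.129 (replicates 8.08 ± 1.67 per Mb, SD, n = 2). Among autosomes the density ran from 35.4 per Mb on chromosome 14 to 69.4 per Mb on chromosome 11. No peak of any list lay on the Y chromosome, which has 183 annotated protein-coding genes. Whether reads were placed there is unknown, so the lack of peaks on Y does not show a lack of the mark. The pools held embryos of both sexes, and the X ratio was 0.101 among peaks above the median fold.

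**Figure D4:**
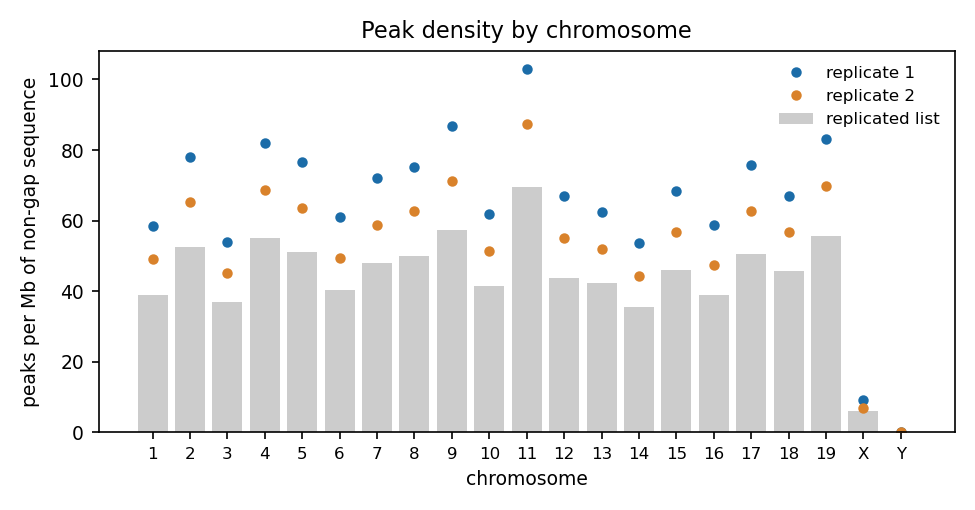
Peaks per Mb of non-gap sequence (vertical axis) for each chromosome (horizontal axis); grey bars show the replicated list, and blue and orange points the lists of replicates 1 and 2. Chromosome X stands at 6.06 per Mb, below the lowest autosome at 35.4.

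The merged stretches with the most bases under H3K4me1 peaks lay over Ssbp3, Gse1 and Tcf20. Ssbp3, which encodes a cofactor of LIM-domain transcription factors, held the first domain, with 75.1 kb covered between 106907366 and 107005196 on chromosome 4 (replicates 65133.5 ± 4442.75 bp, SD, n = 2). The next lay over Gse1 (72.1 kb, chromosome 8; the annotated readthrough gene Gm20388 spans the same place), Tcf20 (54.7 kb), the kinase gene Map4k4 (49.7 kb) and Msi2, an RNA-binding protein gene of neural progenitors (44.9 kb). Ncor2, a corepressor gene, had 44.0 kb, the semaphorin gene Sema6a 43.7 kb, Ccdc85c 42.1 kb, Zmiz1 41.2 kb and Basp1, which encodes a protein of growth cones, 41.1 kb. By span from first to last base, the domains over Msi2 (76.7 kb) and Cmip (75.1 kb) were longer than that over Tcf20 (73.4 kb). Merging gave 54486 domains, of which 416 had at least 10 kb covered. By share of locus, the protocadherin genes Pcdhgc4 and Pcdhgc5, which overlap each other, came first at 63.0% and 61.6%, followed by Basp1 (60.8%), Midn (58.6%) and Pipox (58.1%). The number with at least 10 kb covered was 247 in replicate 2's own list, 193 among peaks above the median fold, 160 with merging within 1 kb and 1277 with the widest merging distance. Of the 20 domains with the most covered bases, 8 overlapped one of the first 20 with merging within 1 kb, 8 with the widest distance and 11 among peaks above the median fold.

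Distal H3K4me1 peaks held more homeodomain and POU sequences than matched places, while the order of the 2 E-box sequences depended on the control. The homeodomain sequence TAATTA was found 0.325 times per kb in distal peaks and 0.201 times in matched places, a log2 ratio of 0.69 ± 0.02 (jackknife standard error), and 0.73 ± 0.04 in the replicates (SD, n = 2). The POU sequence ATGCAAAT had a log2 ratio of 0.66 ± 0.04 and the E-box CAGCTG 0.39 ± 0.02, whereas the E-box CAGATG had 0.02 ± 0.01. The RFX (GTTGCC), NFI (TTGGCA) and ETS (CCGGAA) sequences had 0.24, 0.23 and 0.22, GATA (AGATAA) 0.15 and SOX (ACAATG) 0.10. The HNF4 (CAAAGTC), CTCF (CCACTAG) and AP-1 (TGACTCA) sequences had 0.04 ± 0.02, −0.00 ± 0.03 and −0.06 ± 0.02. Of 87190 distal peaks, 80771 had matched places. Over their reversed sequences, 9 of 12 were higher by more than the 95% bound of the error, among them TAATTA (log2 excess 0.25 ± 0.03), ATGCAAAT (0.75 ± 0.12), both E-boxes (0.49 ± 0.02 for CAGATG and 0.27 ± 0.08 for CAGCTG), ETS (0.26 ± 0.03), CTCF (0.19 ± 0.04), HNF4 (0.13 ± 0.03) and GATA (0.13 ± 0.02). The excess of the ninth, SOX (0.05 ± 0.01), was within that bound in each replicate's own list, among peaks above the median fold and in the central 500 bp of peaks. The other 3 were lower beyond it: NFI (−0.23 ± 0.03), RFX (−0.11 ± 0.03) and AP-1 (−0.06 ± 0.03), of which AP-1 was within the bound in each of the other peak sets and windows and RFX in replicate 2's own list. For CAGATG, CTCF and HNF4 the reversed sequence was itself below matched places, at log2 −0.47, −0.19 and −0.09. Their own ratios were near 0, so their excess came mainly from the control. The reversed sequence of TAATTA still holds ATTA and had a log2 ratio of 0.44, so it is not a control for composition alone. Among other orders of the same bases with as many CpG, 3 of 12 lay in the top 5%: TAATTA (of only 6 orders), ATGCAAAT and TTGGCA. With 6 orders, TAATTA could reach that top 5% only by lying above them all. TAATTA and CAGCTG are palindromes and were ranked only against orders that are not. CAGCTG, at percentile 93.3 of its orders, reached 96.7 in each replicate's own list, in peaks overlapped in both replicates and in the central 500 bp, where TTGGCA fell to 93.3. The sign for TTGGCA, GTTGCC and CCGGAA depended on which control was used, and reversal changes the number of CpG in each of them. It also adds a CpG to ATGCAAAT and CAGCTG, so their excess over the reversed sequence is not a matter of base order alone.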

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

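Tests on the difference between the replicates were chosen after the overall fold, p and overlap of the lists had been seen; those on the X chromosome and on CpG-rich starts were written down before their values were computed, although X peak counts were known.

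In the pooled list, 25219 peaks (13.7%) shared no base with a peak of either replicate, a signal outside the main comparisons; their median fold was 2.23 against 2.77 for other pooled peaks, and 1504 of them were in the replicated list. A further 9 pooled peaks lay on contigs outside the assembled chromosomes and were left out.

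The X chromosome had 0.129 of the autosomal peak density. The tables argue against gene and repeat content, as matched here, as the whole cause. Against autosomal 1 Mb windows of like content, X had 0.324 of the expected peaks, below the lowest single autosome at 0.879. The raw ratio was lower still, so content may account for part of it. The matched windows held 43.9% repeats against 45.3% on X, so the match was close and not exact. Single autosomes held 30.7 to 35.5% repeats, so their ratios do not give the error of a match at the repeat content of X. Of CpG-rich starts, 72.7% on X had a peak within 2.5 kb, against 97.9% on autosomes. For CpG-poor starts the shares were 19.4% and 39.9%. Lower read depth of X in pools of both sexes cannot be told apart from other causes, since the upper quartile of fold was 0.911 of the autosomal value, between the bounds set for and against it. No biological explanation was tested, and X inactivation remains untested.

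CpG-rich starts were covered less than their flanks. The tests argue against poor reading of GC-rich sequence as the whole cause. In 5 equal bins of CpG-rich starts by GC, the dip in the lowest bin was 0.861 of that in the highest. A GC effect would leave it far smaller. Among 2048 GC-rich windows over 5 kb from annotated starts and within 2 kb of a replicated peak, 54.2% were covered. That was 24.5 points more than the sequence 1 kb to either side, the reverse of what low coverage of GC-rich sequence alone would give near peaks. A partial loss of reads cannot be seen this way, and these windows were not matched to the starts on GC. Windows far from any peak were not tested. No biological explanation was tested, and what else occupies these starts cannot be read from a single mark.

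Replicate 1 had more peaks than replicate 2. At fold enrichments from 3 to 3.5 its median −log10 p was 1.18 times that of replicate 2, which is consistent with finer detection through depth or control. Different sites marked in the pools cannot be told apart from this: in the strongest of 5 bins of its peaks 4.26% shared no base with replicate 2, but that bin held 2.08% of all its peaks without a shared base, so it bears little on the weaker peaks that make up the excess. Depth and control cannot be separated here, since read totals were not used here.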

How the results depend on the processing

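Keeping only replicated peaks overlapped in both replicates, using other orders of the same bases as the control for sequences, and matching families of gene symbols on CpG class were alternatives chosen after the data were seen; the rest were planned. For overlap between replicates, lists, families, classes, chromosomes, domains and sequences, 547 values under an alternative kept their side of the threshold or stayed within the spread, 87 moved beyond it, 27 lost a call, 18 gained one and 4 changed direction. The coverage of 85 named genes was counted apart: 60 were lower by over 1 SD in replicate 2's own list and 11 in replicate 1's, 49 with peaks above the median fold, 9 with the stricter q-value, 8 with peaks overlapped in both replicates, 19 with gene bodies alone and 56 with 50 kb on each side, and 2, 5, 0, 0, 0, 29 and 15 were higher. The SD for these genes came from the same 2 replicates' own values, so counts for either replicate's list do not measure robustness beyond the replicates' spread. Many named genes were picked for high coverage by replicated peaks, so lower values in other sets were likely beforehand. Most of the 87 values that moved, counted without the named genes, are shares of the genome. There the SD over 2 replicates was very small for exons (0.033 points) and introns (0.136). It was larger for promoters (0.803) and intergenic sequence (0.972). The causes were not tested except where the construction shows them: fewer or weaker peaks in a list, or a wider window. Depth is unknown, so its effect on weak peaks cannot be given. Using either replicate's own list, promoters held 9.11 to 10.2% of peaks (5.41 to 6.04 times chance), exons 5.59 to 5.64% (1.58 to 1.59 times), introns 54.9 to 55.1% (1.477 to 1.48 times) and intergenic sequence 0.504 to 0.527 times chance. The dip was 39.1 to 41.7 points at CpG-rich starts and 0.468 to 1.18 at CpG-poor starts, with 8.47 to 13.6% and 11.4 to 16.2% covered at the start. The X ratio was 0.118 to 0.132, and domains with at least 10 kb covered numbered 247 to 454. High lists by near-start peaks numbered 9 to 11, with percentiles of 66.9 to 97.6 for pan-neuronal, 99.3 to 99.5 for GABAergic, 99.03 to 99.3 for serotonergic, noradrenergic and motor, and 97.2 to 99.6 for Hox and hindbrain genes; the forebrain locus lay at 96.8 to 99.6. With a q-value of at most 0.0001, shares were 13.1% promoter (7.73 times), 5.97% exon (1.68), 52.6% intron (1.41) and 28.4% intergenic (0.494), and the X ratio was 0.116. With peaks above the median fold they were 15.1% (8.85), 6.63% (1.86), 51.7% (1.39) and 26.6% (0.463). In that set CpG-poor starts were 11.2% covered, the CpG-rich dip was 39.1, the X ratio was 0.101, and 34961 domains included 193 of at least 10 kb. Its locus percentiles were 98.7 for forebrain, 3.06 for liver and 91.5 for dopaminergic genes. With replicated peaks overlapped in both replicates, shares were 12.52% promoter (7.43), 5.96% exon (1.65) and 53.1% intron (1.43), the X ratio was 0.111, and the GABAergic start percentile was 97.9. With a promoter of 2.5 kb, shares were 21.7% (5.25), 3.88% exon (1.18), 46.7% intron (1.29) and 27.8% intergenic (0.492). With all annotated genes they were 14.8% (3.72), 6.34% (1.53), 55.8% (1.33) and 23.1% (0.464). Against a 100 kb shift the ratios were 4.87 for promoters, 1.099 for exons, 1.11 for introns and 0.668 for intergenic sequence, and sharing between replicates was 7.18 and 7.81 times chance. Requiring 75% of both peaks, 15.8% and 19.1% were shared. Ranking pooled peaks by −log10 p, 14.6% of the weakest and 99.9% of the strongest bin were replicated. With a lower CpG limit, CpG-rich starts were 18.3% covered with a dip of 35.8, and CpG-poor starts 9.39% with a dip of 0.010; with every transcript start the dips were 34.7 and 4.32. Matching on CpG class gave 4 high lists for near-start peaks, with percentiles of 92.6 for progenitor, 5.7 for microglia, 92.3 for cell cycle and 65.6 for Irx, Lhx, Pou, Sox and Zic genes. For locus coverage it gave 1.81 for Hox, where the direction turned, 15.9 for liver, 5.0 for vomeronasal and 51.6 for ribosomal protein genes. With a window of 1 kb the start percentile was 98.4 for dopaminergic and 98.6 for GABAergic genes, and with 5 kb it was 99.8 for glutamatergic, 98.7 for serotonergic and 99.1 for Hox genes. With gene bodies alone the locus percentile was 99.8 for forebrain, 1.75 for germ cell and 4.5 for liver genes. With 50 kb on each side it was 93.96 for GABAergic, 11.3 for liver and 62.7 for dopaminergic genes. With means it was 98.98 for forebrain and 2.27 for germ cell genes. Merging within 1 kb left 160 domains of at least 10 kb, and the widest distance gave 32303 domains with 1277 of them. Against other orders of the same bases the log2 excess was 0.28 for TTGGCA, 0.19 for GTTGCC and −0.14 for CCGGAA, each reversed from the planned control.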

Other observations

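The groups and percentiles below were examined after the data had been seen. Replicated peaks covered the gene start itself more often than in random lists matched on gene length and CpG class for 11 of the 24 lists, most of them lists of brain cells or developmental factors. They did so at 19 of 28 midbrain patterning genes, 12 of 20 dopaminergic genes, 9 of 15 GABAergic genes, 12 of 25 Hox and hindbrain genes and 11 of 19 vascular and meningeal genes. Each of these 5 shares lay at percentile 99.985 or higher of the random lists, whose medians ran from 13.3% to 21.1%. The others were the Irx, Lhx, Pou, Sox and Zic family with 25 of 54 (above all random lists), serotonergic, noradrenergic and motor genes with 8 of 14 (99.95), forebrain genes with 9 of 22 (99.83), progenitor genes with 10 of 22 (99.82), astrocyte and ependymal genes with 6 of 12 (99.605) and oligodendrocyte lineage genes with 6 of 14 (99.07). Several of these lists share members, so their calls are not independent. Glutamatergic genes, with 5 of 14, lay just under the bound (97.405). Low lists were liver genes, with 0 of 19 (percentile 2.3), both receptor families and ribosomal protein genes, of which 4 of 96 starts were covered, below all random lists, and 61 of 96 flanked on both sides. None of the 17 cell cycle genes (percentile 4.26) and 1 of 20 pan-neuronal genes (percentile 5.43) was covered at the start, and housekeeping genes were near chance with 3 of 20. Single genes did not all go with their lists: Pitx3, En2, Irx1 and Olig2 were covered and Rpl18 and Mki67 flanked on both sides, but so were Hes5 and Ascl1 of the progenitor list, and Ascl1 is in the GABAergic list too.

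Grouping genes by the letters of their symbol gave 101 families of at least 20 members, of which 25 were high and 16 low in locus coverage against random lists matched on gene length. With matching on CpG class as well, 12 were high and 5 low, 11 and 5 of them also called with length alone; Rpl (percentile 45.7), Rps (77.8) and Polr genes (88.2) were no longer high, and the 5 leading families described next remained so. Histone genes led, with a median of 19.2% of the locus covered (replicates 17.3% ± 2.38, SD, n = 2) and peaks near 59 of 67 starts, followed by Abhd genes (13.8%), Bcl genes (12.7%), semaphorins (12.7%) and the Zbtb zinc finger factors (12.48%). Semaphorins, guidance cues of growing axons, had near-start peaks at 19 of 20 members. Polr genes, which encode RNA polymerase subunits, had them at 28 of 28; these near-start counts were not matched on CpG class. The Pcdhb protocadherins had peaks near none of their 22 starts, in contrast to Pcdhgc4 and Pcdhgc5 farther along the same gene cluster. None of these 22 starts was CpG-rich, while that of Pcdhgc4 was CpG-rich and that of Pcdhgc5 CpG-poor. The locus coverage of Pcdhb genes was not called low (percentile 4.4, or 31.5 with matching on CpG class too). Histone and protocadherin genes are short or repeated in clusters, so neighbouring loci overlap; how reads were placed among similar copies was not tested.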
